A study of Mus musculus with 144 samples.

How the data were processed

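RNA was measured in the hippocampal CA1 area of C57BL6 mice that had received kainate, a glutamate receptor agonist, or NaCl as control, at 6 times between 6 hours and 12 days. The labels number 36 samples, 3 for each of the 12 combinations of treatment and time, and each sample was sequenced as 4 technical replicates, which gave 144 count files. Per the labels' protocols, polyadenylated RNA was reverse transcribed from 10 ng of RNA with the SMART-Seq v4 kit, and libraries came from 180 ng of cDNA with the Nextera XT kit, which does not mark strand. The deposited values are raw counts per Ensembl gene, 44886 genes per file, and the submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.4.0k, SAMtools, HTSeq 0.5.3, DESeq2 1.8.1 and the genome build mm10. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of a gene and of its antisense partner cannot be told apart where they overlap, and near-identical gene copies are uncertain.

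Gene symbols and positions came from GENCODE M21 on GRCm38 (mm10), which held 44048 of the gene identifiers. The other 838 took 0.26% of the counts. Among named genes, exons overlapped those of another gene over 63.5% of Trf, 49.1% of Bcl2a1b, 31.9% of Riox1, 18.8% of Spp1, 13.7% of Lef1, 13.5% of Grin1, 12.8% of Mogat1, 11.5% of Ch25h and 11% of Aldh1l1. Cmss1 and Filip1l, which overlap, took 0.469% and 0.468% of the counts, a ratio of 1.003. Hbb-bs, Hbb-bt and Hba-a2 have near-identical copies, Mt1 and Mt2 are close relatives, and Junos lies antisense to Jun.

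The 4 technical replicates of a sample differed by little more than sampling noise, with a chi-square per degree of freedom between 1.018 and 1.066 (median 1.03), against 12.37 to 580.9 (median 42.915) between samples of one group. They were therefore summed. Summed totals lay between 43.1 and 81.3 M counts per sample, and single files held 10.6 to 20.8 M. The labels do not say that the numbered samples are separate mice, so p-values measure the spread between these samples.

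Summed counts were tested with edgeR 4.0.16 in R 4.3.3, using trimmed-mean (TMM) factors, the default expression filter by group, one fit over the 12 groups with 24 residual degrees of freedom, and quasi-likelihood F-tests. This left 25289 genes, with a common dispersion of 0.061. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene given here comes from that test. Fold changes are log2 values of kainate against the NaCl group of the same time, with the standard error (SE) taken as the absolute log2 fold change over the square root of F. Further F-tests covered a kainate effect at any time, a difference of the kainate effect between times, each time against the time before it, and the 6 NaCl groups over time. No control libraries were shared between times.

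The tests, the alternatives, 41 gene lists and the rule for named genes were chosen before the data were examined. For its largest changes the rule leaves out symbols of predicted genes, RIKEN clones and pseudogenes. At each time it takes the 5 largest rises and the 5 largest falls among called genes whose kainate and NaCl ranges did not overlap and whose higher group averaged at least 5 CPM (counts scaled to a library of 1 M counts). It adds up to 3 members of each list at the time when most of its members were called. Fos, Gfap, Aif1, Wfs1, Ptgs2, Abca1 and Grik1 to Grik5 are added throughout, which gives 162 genes in all. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 246 combinations of list and time, and again with an estimated correlation and with fry. The list members Clec7a and Cebpd were not analysed here.

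On simulated counts with known changes, the gene test at 6 hours recovered 2% of genes changed 1.25-fold, 20% at 1.5-fold, 72% at 2-fold and 98% at 4-fold, with 5 false calls among 101. At 4 days it recovered 2%, 18%, 54% and 98% at these sizes, with 3 false calls among 89. Only 50 genes of each size were changed, in 1 group. The simulation therefore does not test error rates or scaling where most genes differ, as in the real data at 4 days (73.9% called). Per-sample measures were compared by two-sided exact permutation tests of 3 against 3, which cannot go below p = 0.1, and by permutation within times with 100000 resamples.

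Alternatives covered other scalings (RLE, upper-quartile and library totals), no filter or a stricter one, DESeq2 1.42.0, limma voom with and without sample weights, a robust prior, each time alone, all 18 NaCl samples as controls, 1 surrogate variable from sva 3.50.0, pairs of technical replicates, a stricter threshold, a test against a 1.5-fold change, and each sample left out in turn. Leaving out the samples with Ttr above 100 CPM was chosen after seeing the data.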

Results

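CA1 transcripts were counted at 6 times after kainate or NaCl, with 3 samples in each of the 12 groups. Kainate samples had fewer counts at each time: at 6 hours 53.46 ± 9.05 M counts against 78.03 ± 4.83 M (SD, n = 3), and on average -12.79 M over the 6 times (permutation p = 1e-05, the smallest that the permutations can give). The share of counts on mitochondrially encoded genes was higher in kainate by 2.729 percentage points on average, and that of the 50 most abundant genes by 7.845 points, each higher at 6 of 6 times (permutation p = 1e-05 for both). With library totals alone, all 11 mitochondrially encoded genes of the fixed list were called higher at 1 day. Only 4 were at 4 days and 3 at 6 days, so a rise was not shown for most of them there. The cause of the higher share was not tested. The share of protein-coding genes changed by -3.605 points (lower at 6 of 6 times), that of Cmss1, Lars2 and CT010467.1 higher by 1.065 points (6 of 6 times), and 2397 more genes had at least 10 counts (5 of 6 times; permutation p = 1e-05, 1e-05 and 2e-05). The series is titled for lipid signaling during neuronal degeneration, and the comparisons ask what kainate changed at each time and which changes differed between times.

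Few genes differed at 6 hours, and most genes tested differed at every later time. At 6 hours 888 genes were higher and 946 lower in kainate, 7.3% of the 25289 tested. The counts were 9177 higher and 7629 lower at 1 day, 9848 and 8045 at 2 days, 9573 and 9116 at 4 days, 9467 and 9056 at 6 days, and 10002 and 8649 at 12 days. The balance depended on the scaling: higher genes made up 54.6%, 55%, 51.2%, 51.1% and 53.6% of the calls from 1 to 12 days, but 66.9%, 71.1%, 66.1%, 64.3% and 64.2% with library totals alone. With upper-quartile factors the share was 63.8% at 4 days and 62.9% at 6 days. The median of all genes lay at 0.26, 0.30, 0.18, 0.26 and 0.30 on the log2 scale at these times and at 0.59, 0.81, 0.72, 0.75 and 0.68 with library totals. With the stricter filter it lay at 0.05, 0.06, 0.02, 0.02 and 0.07. This median thus depends on the scaling and on the genes kept.

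**Figure D1:**
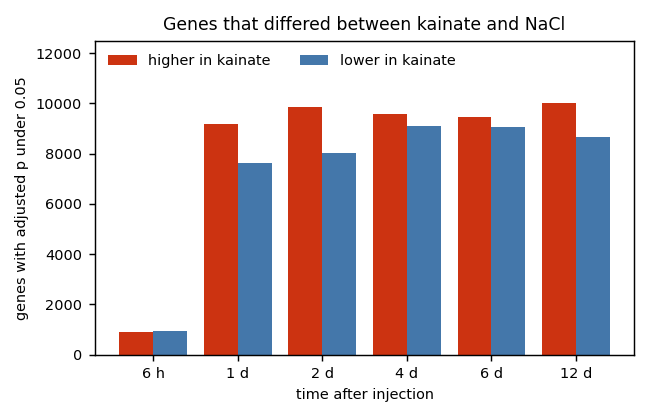
Bars give the number of genes higher (red) and lower (blue) in kainate than in NaCl at each time after injection, at an adjusted p under 0.05 in edgeR's quasi-likelihood test. The bars reach 888 and 946 genes at 6 hours and 10002 and 8649 genes at 12 days.

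At 6 hours the transcripts of genes that neurons switch on within minutes of activity stood highest. Npas4, an activity-dependent transcription factor, rose from 33.4 ± 9.86 to 1220 ± 293 CPM (SD, n = 3), a log2 fold change of 5.19 ± 0.79 (SE, adjusted p = 4.52e-05, edgeR). Fos rose by 4.89 ± 0.46, Gadd45g by 4.63 ± 0.34 and Jun by 4.32 ± 0.34. Fos lies at chromosome 12:85473890-85477273 on the plus strand, Jun at chromosome 4:95049034-95052222 on the minus strand and Npas4 at chromosome 19:4984355-4990316 on the minus strand. Junos rose by 4.13 ± 0.32, but it lies antisense to Jun and 5.6% of its exon bases overlap those of Jun, where reads cannot be told apart. The largest falls named were in Cdca4 (-2.24 ± 0.22), Hps6 (-2.21 ± 0.25), Dyrk3 (-2.21 ± 0.22), Ttc30b (-2.15 ± 0.22) and Riox1 (-2.06 ± 0.14). Dyrk3 was also high in the NaCl group of 6 hours, with 87.5 CPM against 34.3 to 61.8 in the other NaCl groups, and its fall was -1.44 against all 18 NaCl samples.

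Of the 30 immediate early and activity genes, 18 rose at 6 hours and none fell, with 24 higher when adjusted over the list alone. Camera gave an adjusted p of 8.9e-47, and the call held with an estimated correlation (adjusted p = 0.0215). Of the 15 heat shock and chaperone genes 3 rose (4 adjusted over the list alone), with Hspb1 at 1.99 ± 0.35 (adjusted p = 3.00e-04). Of 16 interneuron genes 4 fell (5 adjusted over the list alone), among them the parvalbumin gene Pvalb (-1.14 ± 0.30) and Lhx6 (-1.75 ± 0.33). Camera called both lists (adjusted p = 0.00511 and 0.00146), and both calls were lost (adjusted p = 0.497 and 0.471 with an estimated correlation). It also called the choroid plexus, astrocyte, reactive astrocyte, oligodendrocyte, lysosome and thalamus lists, where only 2, 1, 2, 2, 2 and 2 members were called, with 9 choroid plexus genes and otherwise the same counts adjusted over the list alone. Kainate sample 4 stood apart in some of them, with a mean log2 CPM of 2.57 for the choroid plexus list against at most -1.65 in samples 5 and 6, and 2.79 for the thalamus list against 1.90 and 1.96. These calls were lost too (adjusted p = 0.599, 0.603, 0.696, 0.653, 0.727 and 0.45 with an estimated correlation).

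Most markers of CA1 neurons, astrocytes and microglia did not pass the test at 6 hours, with 1 of 14 CA1 genes higher and none lower, also adjusted over the list alone. Wfs1, a CA1 pyramidal neuron marker, had 1230 ± 47.5 CPM in NaCl and 1130 ± 36.3 in kainate (SD, n = 3), and Gfap, the astrocyte filament gene, stood at 0.20 ± 0.41 (adjusted p = 0.882). The 20 pan-neuronal genes and the 15 homeostatic microglia genes had no call, also when adjusted over the list alone. Camera called as many lists or more in some other splits of the 6 samples at each time, and the gene counts at 6 hours rested partly on single samples: without kainate sample 4 there were 495 higher and 572 lower genes, and without NaCl sample 2 there were 504 higher.

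At 1 day CA1 and pan-neuronal transcripts were lower and those of glia, of stress responses and of cell death genes were higher. Wfs1 (chromosome 5:36966104-36989205, minus strand) fell from 943 ± 163 to 177 ± 130 CPM (SD, n = 3; log2 fold change -2.41 ± 0.36, adjusted p = 1.42e-06, edgeR). Hspb1, a small heat shock protein gene, rose by 6.82 ± 0.41 to 430 ± 88.2 CPM. Fos stood at 5.18 ± 0.47 and Gadd45g at 5.13 ± 0.35. Large falls were those of Lct (-5.01 ± 0.54), Sprn (-4.93 ± 0.49), Neurod6 (-4.86 ± 0.65), Rimbp3 (-4.82 ± 0.30) and Kcnv1 (-4.61 ± 0.82).

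Among large rises at 1 day, Areg, a ligand of the EGF receptor, rose by 10.48 ± 1.49 and Muc3 by 9.19 ± 0.83. Rln3 had no counts in the NaCl samples and 14.4 ± 10.8 CPM in kainate, at least 821-fold higher against a floor of 3 counts over the group. Tac1, which encodes a substance P precursor, rose by 4.40 ± 0.56 to 342 ± 228 CPM. Ttr (12.83 ± 3.31), Folr1 (9.23 ± 2.05) and Clic6 (8.39 ± 1.95), genes of the choroid plexus, rested on kainate sample 10. Without that sample their log2 fold changes were 2.23, 2.88 and 2.16, and none passed the test. The choroid plexus list had 10 of 12 genes higher and 1 lower at 1 day (10 and 1 adjusted over the list alone), and camera did not call it (adjusted p = 0.413).

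Most neuronal lists fell at 1 day, to a different extent in each sample: the mean log2 CPM of the CA1 list was 4.38, 5.92 and 6.84 in kainate samples 10, 11 and 12, against 8.31 in NaCl. The CA3 and CA2 list and the dentate granule neuron list did not fall, with median log2 fold changes of 1.01 and 0.27. Of 20 pan-neuronal genes 17 fell, of 14 CA1 pyramidal neuron genes 13 fell, and of 33 channel and GABA receptor genes 31 fell and 1 rose, with the same counts adjusted over the list alone. Their camera calls were lost (adjusted p = 0.497, 0.556 and 0.497 with an estimated correlation). Of the interneuron genes 11 fell and 1 rose (12 and 1 adjusted over the list alone), with Pvalb at -4.19 ± 0.34 and the rise being that of Tac1. With library totals alone 8 fell and 3 rose. The camera call of this list was lost as well (adjusted p = 0.535 with an estimated correlation). The lists of growth factors and neuropeptides (10 of 21 higher, 2 lower; the same adjusted over the list alone) and of neural progenitors (7 of 11 higher, 1 lower; 7 and 2 adjusted over the list alone) were not called by camera (adjusted p = 0.151 and 0.116).

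Stress and cell death genes rose at 1 day. Of 21 apoptosis and p53 target genes 17 rose and 1 fell (the same adjusted over the list alone), among them Cdkn1a, a cell cycle inhibitor (4.48 ± 0.39). Of 17 oxidative stress genes 15 rose and 1 fell, and of 17 genes of endoplasmic reticulum stress 11 rose and 1 fell, each with the same counts adjusted over the list alone. Mt2 rose by 4.11 ± 0.43 and Trib3 by 4.28 ± 0.48. The 3 camera calls were lost (adjusted p = 0.45 with an estimated correlation for each). Astrocyte identity genes were higher in 16 of 16 cases (Mlc1 at 2.26 ± 0.31) and oligodendrocyte and myelin genes in 16 of 16 (Cldn11 at 3.39 ± 0.26), the same adjusted over the list alone, and these calls were lost too (adjusted p = 0.497 and 0.45 with an estimated correlation).

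Among lipid genes at 1 day, 16 of 27 genes of lipid droplets and triglycerides rose and 6 fell (17 and 6 adjusted over the list alone, 3 lower with library totals alone; camera adjusted p = 0.0541, not called). Mogat1, an enzyme of diacylglycerol synthesis at chromosome 1:78510991-78538173, rose from 0.274 ± 0.0827 to 50.2 ± 35.2 CPM (SD, n = 3; 7.51 ± 0.61). Plin2, which coats lipid droplets, rose by 4.39 ± 0.59 and Cd36, a fatty acid transporter, by 3.27 ± 0.52. Ptgs2, the inducible cyclooxygenase gene at chromosome 1:150100031-150108227, rose by 2.99 ± 0.59 to 204 ± 152 CPM. Hemoglobin genes were higher as well, with 5 of 5 red blood cell genes called, also when adjusted over the list alone (camera adjusted p = 0.0506, not called). Of 11 mitochondrially encoded genes 7 rose, 7 adjusted over the list alone, 11 with library totals alone, with mt-Rnr2 at 2.27 ± 0.28; the camera call was lost (adjusted p = 0.57 with an estimated correlation).

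At 2 days CA1 neuron transcripts were far lower, and microglial, interferon and vascular transcripts were higher. Fibcd1, a CA1 marker at chromosome 2:31813290-31846005, fell from 761 ± 19.4 to 5.16 ± 3.92 CPM (SD, n = 3; -7.21 ± 0.61, adjusted p = 3.55e-11, edgeR). Spp1, which encodes osteopontin (chromosome 5:104435118-104441050), rose from 6.79 ± 7.49 to 6630 ± 1310 CPM (9.93 ± 0.95), and Cd5l rose by 9.22 ± 0.75. Other large falls were Ankrd63 (-8.74 ± 0.77), Htr1a, a serotonin receptor gene (-7.81 ± 0.62), Htr5b (-7.02 ± 0.27) and Alox12b (-6.85 ± 0.53). Serpinb2 rose by 10.00 ± 1.46 and Krt75 by 8.77 ± 1.60, and Lce1g had no counts in NaCl and 11.5 ± 17.1 CPM in kainate, at least 682-fold higher against the same floor. The size of these 3 rises rests on kainate sample 16, with 54.5 CPM of Serpinb2, 16.9 of Krt75 and 31.2 of Lce1g against at most 3.72, 0.367 and 3.30 in the other kainate samples.

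The mean log2 CPM of the CA1 list at 2 days was 4.98, 2.66 and 3.53 in kainate samples 16, 17 and 18, against 8.37 in NaCl. The CA1 list fell in 14 of 14 genes and the pan-neuronal list in 20 of 20 at 2 days, also adjusted over the list alone (adjusted p = 0.45 with an estimated correlation, which ends both camera calls). All 22 interferon response genes rose, also adjusted over the list alone, with Ifit3 at 5.07 ± 0.71 and Irf7 at 5.01 ± 0.74 (adjusted p = 0.556 with an estimated correlation). Kainate levels of this list did not stand higher than at 1 day. Its mean log2 CPM in kainate lay at 6.07 to 6.49, against 5.58 to 7.17 at 1 day. In NaCl it lay at 1.60 to 3.47, against 1.65 to 5.85 at 1 day. Endothelial genes rose in 14 of 14 cases (Pecam1 at 4.14 ± 0.34), mural and fibroblast genes in 14 of 14 (Dcn at 5.05 ± 0.47) and oligodendrocyte precursor genes in 11 of 11 (Olig2 at 3.11 ± 0.28), the same adjusted over the list alone. The thalamus and white matter list rose in 7 of 7 genes, also adjusted over the list alone, with Tcf7l2 at 2.35 ± 0.22. Camera called these 4 lists, and the calls were lost (adjusted p = 0.45 with an estimated correlation for each). Of 15 heat shock genes 7 were higher and 8 lower (the same adjusted over the list alone; camera adjusted p = 0.442, not called), but only 2 were lower with library totals alone, where the list median was 0.06 against -0.44.

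Cholesterol biosynthesis genes rose at 1 and 2 days. At 2 days 21 of 25 were higher and 2 lower, the same adjusted over the list alone, and at 1 day 18 were higher and 1 lower (18 and 2 adjusted over the list alone). Msmo1, a sterol oxidase gene at chromosome 8:64718139-64733792, rose from 83.3 ± 4.79 to 310 ± 86.5 CPM at 2 days (SD, n = 3; 1.89 ± 0.17, adjusted p = 7.30e-11, edgeR). Stard4 rose by 1.99 ± 0.24. Camera called the list at both times (adjusted p = 0.0159 and 0.00051), and the calls were lost (adjusted p = 0.599 and 0.497 with an estimated correlation). Endocannabinoid genes (5 of 15 higher, 9 lower) and phosphoinositide and diacylglycerol genes (24 of 46 higher, 19 lower) went both ways at 2 days, with the same counts adjusted over the list alone, and were not called by camera (adjusted p = 0.225 and 0.996). With library totals alone 6 and 25 were higher and 6 and 17 lower. Dagla, which makes the endocannabinoid 2-arachidonoylglycerol, fell by 2.92 ± 0.27, Faah fell by 3.86 ± 0.47 and Itpka fell by 5.37 ± 0.51.

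**Figure D2:**
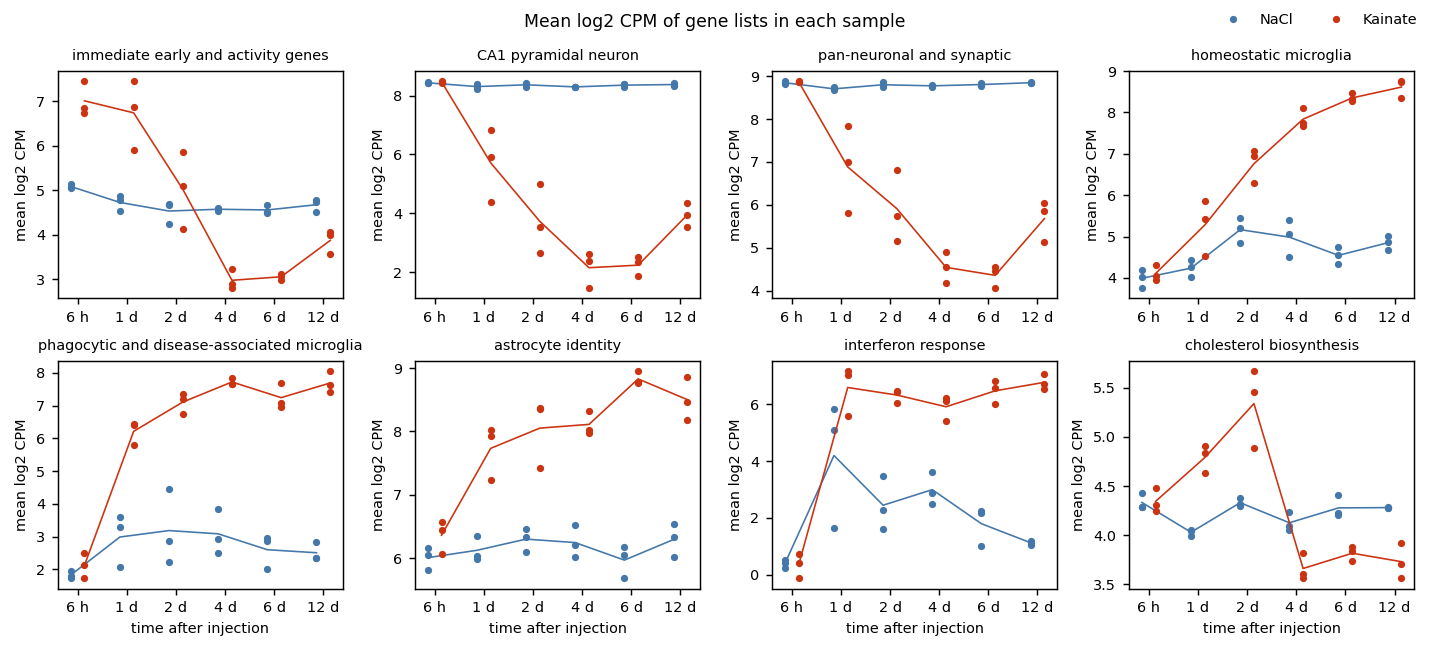
Each panel plots the mean log2 CPM of a gene list against time after injection, with a point per sample (3 per group) and a line through the group means, NaCl in blue and kainate in red. The neuronal panels fall in kainate from 1 day on, the glial and interferon panels rise, and cholesterol biosynthesis rises at 1 and 2 days and lies under NaCl from 4 days.

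At 4 days the CA1 and pan-neuronal transcripts stood at or near their lowest level and genes of microglia, lysosomes and cell division were higher. Htr1a fell by 10.39 ± 0.75, from 103 ± 3.99 to 0.0733 ± 0.0452 CPM (SD, n = 3; adjusted p = 9.33e-13, edgeR), and Fibcd1 fell by 9.15 ± 0.66. Spp1 rose by 10.76 ± 0.98 and Cd5l, a macrophage gene, by 11.16 ± 0.70. Msr1, a scavenger receptor gene, rose by 7.28 ± 0.94, Ch25h, the cholesterol 25-hydroxylase gene, by 7.13 ± 0.83, and Oas1g by 7.10 ± 0.85. Falls were also large in Cpne6 (-8.75 ± 0.59), Egr3 (-8.27 ± 0.79) and Itpka (-8.25 ± 0.58).

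Homeostatic microglia genes rose in 15 of 15 cases at 4 days and lysosome genes in 26 of 28 with 1 lower, the same adjusted over the list alone. Aif1, which marks microglia and macrophages (chromosome 17:35170991-35176068), rose from 20.6 ± 2.14 to 247 ± 27.8 CPM (SD, n = 3; 3.59 ± 0.35), and Ctsd, a lysosomal protease gene (chromosome 7:142375911-142388038), from 411 ± 132 to 12700 ± 2320 CPM (4.95 ± 0.31). Of 24 proliferation genes 24 rose, also adjusted over the list alone, with Mki67 at 4.78 ± 0.52 and Birc5 at 4.46 ± 0.38. These camera calls were lost (adjusted p = 0.45 with an estimated correlation for each).

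Glutamate receptor subunit genes fell in 16 of 22 cases and rose in 5 at 4 days, the same adjusted over the list alone, with Gria1 at -6.29 ± 0.58 and Grin2a at -5.91 ± 0.62 (adjusted p = 0.563 with an estimated correlation). The dentate granule neuron list went both ways, with 4 of 10 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.731, not called). Calb1 fell by 6.92 ± 0.84 and Npnt rose by 2.91 ± 0.33. Eicosanoid genes were higher in 26 of 36 cases and lower in 8 (27 and 8 adjusted over the list alone, 5 lower with library totals alone), with Tbxas1, the thromboxane synthase gene, at 4.31 ± 0.32 and Alox12b at -7.92 ± 0.58. Fatty acid oxidation genes were higher in 23 of 30 cases and lower in 4 (the same adjusted over the list alone, 25 and 2 with library totals alone), with Ucp2 at 3.98 ± 0.40. Both calls were lost (adjusted p = 0.45 and 0.519 with an estimated correlation).

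At 6 days the changes resembled those at 4 days, and 195 genes differed between the kainate effects of these times. Gfap (chromosome 11:102887336-102900912) rose from 197 ± 74.7 to 5710 ± 742 CPM (SD, n = 3; 4.85 ± 0.48, adjusted p = 4.58e-10, edgeR). Abca1, a cholesterol exporter gene at chromosome 4:53030787-53159895, rose from 32.1 ± 1.53 to 348 ± 32.9 CPM (3.44 ± 0.18). Klk6 rose by 8.61 ± 0.77, Sucnr1 by 8.42 ± 0.77 and the chemokine gene Cxcl10 by 8.03 ± 1.32. Large falls were those of Fibcd1 (-9.48 ± 0.67) and Cpne6 (-9.14 ± 0.60). Of the immediate early and activity genes 8 were higher and 19 lower at 6 days, also adjusted over the list alone, with Arc at -6.18 ± 0.82 and Egr4 at -7.17 ± 0.79 (camera adjusted p = 0.153, not called).

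Reactive astrocyte genes rose in 23 of 23 cases at 6 days (Timp1 at 7.68 ± 0.90), complement and antigen presentation genes in 21 of 22 (C3 at 5.71 ± 0.96) and chemokines and cytokines in 25 of 28 with 2 lower (Ccl3 at 6.91 ± 1.12), the same adjusted over the list alone. Kainate levels of the reactive astrocyte and chemokine lists did not stand higher than at 1 day. Their mean log2 CPM lay at 6.39 to 6.55 and 3.10 to 3.53, against 6.32 to 7.18 and 4.70 to 5.50 at 1 day. In NaCl it lay at 1.04 to 2.15 and -0.84 to 0.25, against 2.20 to 4.97 and 0.48 to 3.86 at 1 day. The complement list in kainate lay higher, at 6.23 to 6.62 against 4.11 to 5.06 at 1 day. Cholesterol transport and oxysterol genes rose in 18 of 25 cases and fell in 5 (the same adjusted over the list alone, 20 and 3 with library totals alone), with Ch25h at 7.76 ± 0.89 and Apoc1 at 6.06 ± 0.66. Camera called these 4 lists, and the calls were lost (adjusted p = 0.454, 0.45, 0.535 and 0.45 with an estimated correlation). Fatty acid synthesis and elongation genes went both ways, with 13 of 26 higher and 9 lower (the same adjusted over the list alone, 17 higher and 6 lower with library totals alone). Camera did not call the list (adjusted p = 0.285). Elovl1 stood at 3.38 ± 0.31 and Elovl4 at -3.06 ± 0.41.

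At 12 days microglial and interferon transcripts stood high, and CA1 transcripts stayed low. The mean log2 CPM of the interferon list in kainate, 6.54 to 7.08, lay within its range at 1 day (5.58 to 7.17). In NaCl it was 1.05 to 1.19, against 1.65 to 5.85 at 1 day. Cst7, a microglial cystatin gene (chromosome 2:150570415-150578944), rose from 0.886 ± 0.654 to 709 ± 181 CPM (SD, n = 3; 9.64 ± 0.69, adjusted p = 1.01e-12, edgeR). Ccn5 rose by 11.77 ± 0.81 and Ifi27l2a by 10.02 ± 0.94. Apoc4 and Phf11a had no counts in NaCl and 7.65 ± 3.18 and 6.76 ± 1.60 CPM in kainate, at least 461-fold and 407-fold higher against the same floor. The largest falls named were Alox12b (-8.69 ± 0.62), Htr1a (-8.64 ± 0.66), Lct (-7.47 ± 0.62), Egr3 (-6.67 ± 0.69) and Scn4b (-6.64 ± 0.54).

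Phagocytic and disease-associated microglia genes rose in 22 of 22 cases at 12 days, with Gpnmb at 6.63 ± 0.87, and infiltrating leukocyte genes in 15 of 16, with Mrc1 at 2.79 ± 0.33, the same adjusted over the list alone. The camera calls were lost (adjusted p = 0.45 and 0.497 with an estimated correlation). Levels of the infiltrating leukocyte list were low. Its mean log2 CPM at 12 days lay at 0.44 to 1.09 in kainate, with a group mean of -2.903 in NaCl. Only Nkg7 and Mrc1 were named from this list. Whether leukocytes had entered the tissue was not tested. Sphingolipid genes were higher in 24 of 40 cases and lower in 14, also adjusted over the list alone, with 9 lower with library totals alone (camera adjusted p = 0.127, not called), with S1pr3 at 4.62 ± 0.52 and Smpd3 at -2.70 ± 0.31. The CA3 and CA2 list went both ways, with 5 of 11 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.995, not called); Pcp4 rose by 4.17 ± 0.86 and Amigo2 by 3.25 ± 0.73. Cholesterol biosynthesis genes were lower in 15 of 25 cases and higher in 3, also adjusted over the list alone (camera adjusted p = 0.0567, not called), with Msmo1 at -0.77 ± 0.16; with library totals alone 10 were lower and 6 higher.

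**Figure D3:**
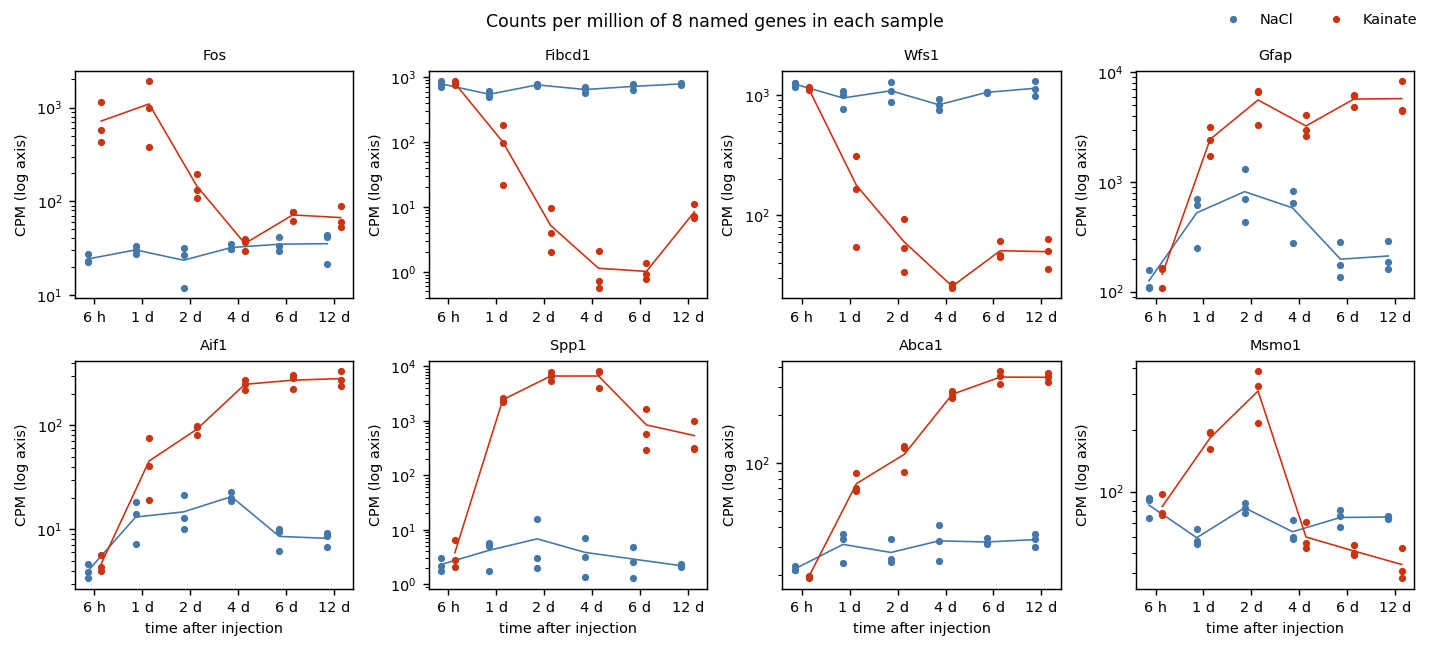
Each panel plots the CPM (log axis) of a gene against time after injection, with a point per sample (3 per group) and a line through the group means. Fos reaches 719 and 1090 CPM in kainate at 6 hours and 1 day, Fibcd1 falls to 1.01 CPM at 6 days, and Spp1 reaches 6640 CPM at 4 days.

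The kainate effect differed between times for 17085 genes, 67.6% of those tested, in edgeR's test over 5 contrasts. Against the time before, it changed for 12093 genes at 1 day, 3106 at 2 days, 1862 at 4 days, 195 at 6 days and 120 at 12 days. In all, 22794 genes (90.1%) had an effect at some time. Of all genes tested, 5477 genes were higher and 5825 lower at each of the 5 times from 1 to 12 days, and 376 and 529 at all 6 times. Of the 888 genes higher at 6 hours 592 were also higher at 1 day and 106 were lower, where independent lists would share 322; of the 946 lower genes 636 were also lower and 90 higher, where 285 would be shared.

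Several genes were called in opposite directions at different times. Npas4 rose by 5.19 at 6 hours and fell by 4.98 at 4 days, and Tac1 rose by 4.40 at 1 day and fell by 5.89 at 6 days (adjusted p of the difference between times 3.41e-09 and 2.54e-10, edgeR). Ptgs2 stood at 0.64 ± 0.55 at 6 hours (adjusted p = 0.616), rose at 1 and 2 days (2.99 ± 0.59 and 2.22 ± 0.57), fell at 4 and 6 days (-1.64 ± 0.57 and -2.69 ± 0.61) and stood at -0.32 ± 0.55 at 12 days (adjusted p = 0.612). The rise at 2 days was 1.11 without kainate sample 16 and no longer passed. Abca1 stood at -0.18 ± 0.17 at 6 hours (adjusted p = 0.663) and rose by 1.27, 2.05, 3.06, 3.44 and 3.39 at the later times.

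The kainate receptor subunit genes differed from each other. Grik5 (chromosome 7:25009849-25072346) fell at each time from 1 day, to -2.03 ± 0.27 at 4 days, though the call at 1 day (-0.81 ± 0.26) was lost without kainate sample 10 (-0.44). Grik2 (chromosome 10:49094833-49788766) fell at 1, 2 and 4 days (-1.05 ± 0.19, -0.71 ± 0.19 and -0.55 ± 0.19), and with library totals alone its value at 4 days was 0.01. Grik3 rose from 1 to 6 days, by 1.82 ± 0.27 at 4 days, and Grik4 rose at 1, 2, 6 and 12 days, by 2.00 ± 0.26 at 12 days. Grik1 rose at 2 days (0.77 ± 0.26) and 4 days (1.36 ± 0.27). Levels of Grik1, Grik3 and Grik4 were low, with 2.59, 2.60 and 10.4 CPM in NaCl at 4 days.

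**Figure D4:**
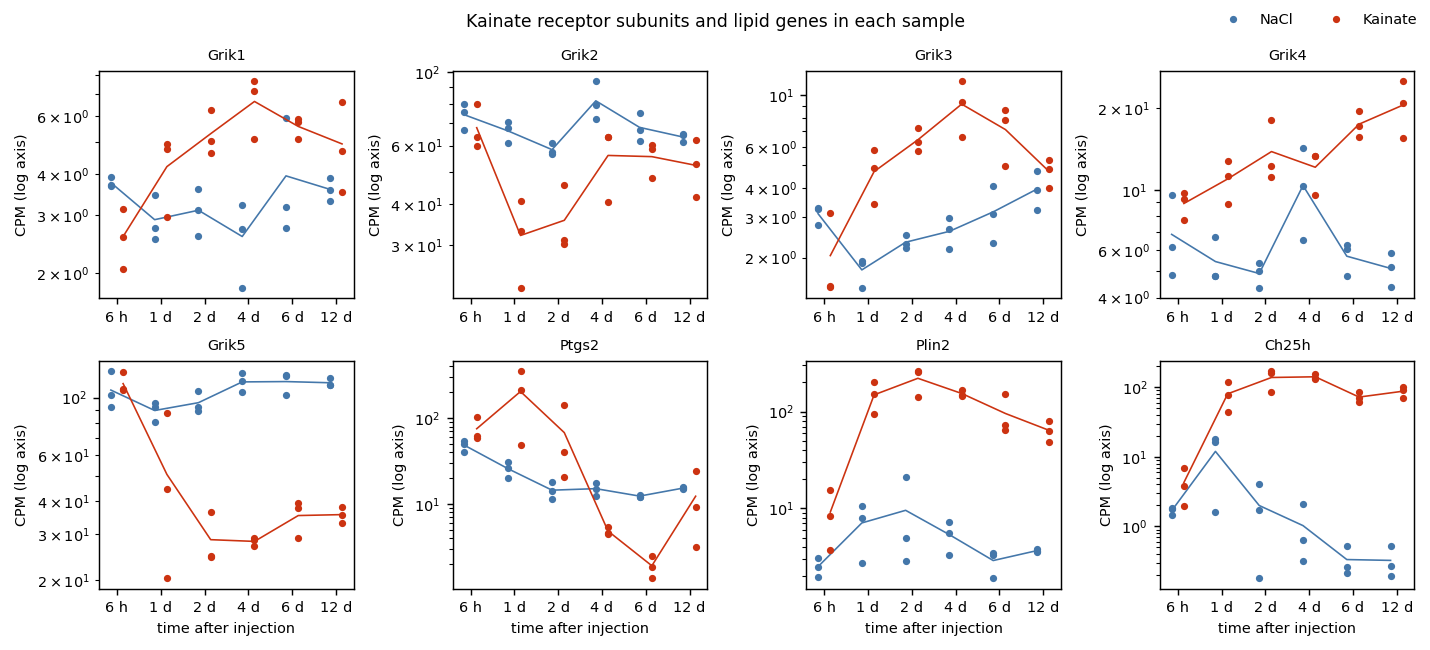
Each panel plots the CPM (log axis) of a kainate receptor subunit or lipid gene against time after injection, with a point per sample (3 per group) and a line through the group means. Grik5 lies at 28.1 CPM in kainate and 115 CPM in NaCl at 4 days, and Ptgs2 passes from 204 CPM at 1 day to 1.92 CPM at 6 days.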

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

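Tests chosen only after the result was seen were those of the scaling and of the neuronal share for the neuronal transcripts, both tests of the choroid plexus transcripts, the tests of the neuronal share and of the scaling for the cholesterol genes, and the splits at single times. The others (thinning, correction for GC content and length, and splits over all times) were set before their result was seen.

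The kainate effect differed between times for 17085 genes, and from the time before for 12093 genes at 1 day, 3106 at 2 days, 1862 at 4 days, 195 at 6 days and 120 at 12 days. Of 31 regroupings of the samples, the real one included, 1 gave as many calls in each of these tests, the real one. The highest counts of the others were 0, 17, 0, 0, 0 and 47. In these tests the samples of a treatment were mixed over all 6 times. This argues against chance for a difference between times as a whole. It cannot exclude chance for a single step between neighbouring times, since the mixing joined unlike times within a group. For an effect at any time, treatment labels were instead shuffled within each time. The real count was 22794 and the highest other 17745, with 1 of 31 as large. Such a draw can keep the real split at some times, so the 17745 can hold real differences between kainate and NaCl. With samples mixed over times again, the counts for the NaCl groups over time were 2390 and 0. For NaCl at 6 hours against the other NaCl groups they were 2043 and 54, each with 1 of 31 as large.

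At single times the 6 samples allow 10 splits, too few for a share under 0.05. The real and the highest other count of genes were 1834 and 0 at 6 hours, 16806 and 306 at 1 day, 17893 and 1137 at 2 days, 18689 and 0 at 4 days, 18523 and 0 at 6 days, and 18651 and 0 at 12 days, with 1 split as large each. Counts of gene lists called by camera did not set the real split apart: 9 against a highest other of 21 at 6 hours, 26 and 28 at 1 day, 27 and 30 at 2 days, 25 and 25 at 4 days, 24 and 29 at 6 days, and 25 and 26 at 12 days. As many lists were called in 5, 4, 4, 6, 7 and 3 of the 10 splits.

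Of the 162 named genes 155 differed between times. The 11 genes named at every time and those called in both directions differed by the following spans of log2 fold change between their lowest and highest times. Spans were 3.61 for Abca1, 4.88 for Aif1, 9.54 for Arc, 2.88 for Cdca4, 9.00 for Egr4, 5.04 for Fos, 4.66 for Gfap, 2.66 for Msmo1, 11.1 for Nkg7, 10.17 for Npas4, 5.68 for Ptgs2, 10.29 for Tac1, 21.1 for Ttr and 4.89 for Wfs1. The span of Ttr rests on kainate sample 10 at 1 day and on NaCl sample 25 at 6 days, weighed below. Among the kainate receptor subunits they were 1.90 for Grik1, 0.92 for Grik2, 2.41 for Grik3, 1.78 for Grik4 and 2.12 for Grik5. No test for outlying samples was run in these groups of 3. Each sample was left out in turn for the fold changes at the times that the rule named, but not for the spans.

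CA1 and pan-neuronal transcripts were lower and non-neuronal ones higher from 1 day on. With library totals alone the median of the pan-neuronal genes at 4 days was -4.04, against -4.58 with TMM factors. All genes shared this shift, with a median of 0.72 and 0.18, so the factors fixed the outcome. The values show only that the choice between these scalings makes up a small part of the fall. With every sample thinned to the lowest total, 43114229 counts, 20 of 20 pan-neuronal genes were still called lower, which argues against depth. A lower share of neurons with no other change would raise markers of other cells alike, provided that neurons do not transcribe them. Whether neurons do was not tested for these lists. Relative to the astrocyte score, the homeostatic microglia score changed by -0.57 ± 0.18, -0.16 ± 0.11, 0.99 ± 0.13, 0.95 ± 0.12 and 1.56 ± 0.24 (SE) from 1 to 12 days. The score of phagocytic microglia changed by 1.61 ± 0.39 at 1 day already and by 2.77 ± 0.26 at 4 days. Under that condition the values from 4 days on, and those of phagocytic microglia, argue against the explanation. At 1 and 2 days the endothelial score rose by 0.39 ± 0.08 and 0.91 ± 0.09 more than that of astrocytes. Under the same condition this argues against the explanation there too. The endothelial list was taken from 5 after their values were seen. The oligodendrocyte score moved with that of astrocytes at 2 and 4 days, with differences of 0.07 ± 0.14 and -0.13 ± 0.12. It moved apart from it at 1 and 6 days, with 0.58 ± 0.1 and -0.5 ± 0.13. A loss of CA1 neurons together with changes in other cells may underlie the pattern, as a hypothesis found and tested on the same data.

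Choroid plexus transcripts stood out in kainate samples 4 and 10 and in NaCl sample 25, with 328, 3000 and 432 CPM of Ttr against at most 3.57 CPM in the other samples. Of 5 other genes of the choroid plexus list, at least 4 lay above every other sample in each of the 3. A response to kainate is argued against by the other kainate samples at 6 hours and 1 day, whose highest Ttr was 0.92 CPM, and by the NaCl sample. Choroid plexus tissue taken along in dissection may account for these values.

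Cholesterol biosynthesis transcripts were higher at 1 and 2 days, and with TMM factors lower later. A lower share of neurons alone would move a gene one way as that share falls, but the median change from 2 to 4 days was -1.47, with 23 of 25 genes called as fallen. This was the later of a pair of tests tried: in the first, whose value was seen before it was replaced, the list median at 2 days lay 0.69 above that of all genes, which also argued against the explanation but could not decide, since glia and neurons both transcribe these genes. Neither test covers a changed mix of the other cells. Relative to the astrocyte score, the homeostatic microglia score went from -0.16 at 2 days to 0.99 at 4 days. The endothelial score went from 0.91 to 0.31. A shift in that mix thus cannot be told apart from a change within cells. After a correction for GC content and exon length, 22 of 25 genes were called higher at 2 days, which argues against such bias. Whether the genes fell later cannot be told apart from the scaling: the list median at 12 days was -0.61 with TMM factors and -0.24 with library totals alone, a shift that all genes shared. Relative to the median of all genes, which itself depends on the filter, the list median lay at -0.91 and -0.92.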

How the results depend on the processing

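The alternative chosen only after the data were seen left out the samples with choroid plexus transcripts; all others were fixed beforehand. No paired analysis was possible because the labels number the samples 1 to 36 with no number shared between groups. Of 240 values of named genes at given times, 213 kept their direction and side of the threshold under the 17 alternatives and with each sample left out; fitting each time alone and the stricter filter gave 237 and 238 of them. Counts of genes moved by over 1.5 times as follows, and the cause was not tested unless given. At 6 hours, 888 higher and 946 lower genes became 2080 and 2120 with voom and sample weights, 156 and 96 against a 1.5-fold change and 433 and 545 at an adjusted p under 0.01, both stricter by construction. Lower genes at 6 hours were 1658 with each time alone and 1777 with all 18 NaCl samples. With single samples left out at 6 hours, higher genes ranged from 495 (without kainate sample 4; 504 without NaCl sample 2) to 860 and lower genes from 572 (without kainate sample 4) to 844. Lower genes were 4968 at 1 day against a 1.5-fold change and 5270 at 2 days with library totals alone, and voom called 1452 genes in the NaCl test over time. At 6 hours camera called 9 lists with the preset correlation and 1 with an estimated one. Fry called 4 there, with 3 of the 9 among them. At 1, 2, 4, 6 and 12 days camera called 0 lists with an estimated correlation. The adjusted p of the lists called with the preset one then lay between 0.45 and 0.683. Fry called 37, 34, 34, 36 and 34 of 41 lists at these times. They held all 26, 27, 25, 24 and 25 lists that camera called with the preset correlation, in the same direction. Fry does not compare a list with the other genes, most of which differed at these times. Without the choroid plexus samples, higher and lower genes were 635 and 727, 8464 and 7356, 10096 and 8232, 9814 and 9304, 9480 and 8965, and 10229 and 8815 from 6 hours to 12 days.

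Values that reversed lay near 0 or rested on other controls. With all 18 NaCl samples, Gfap, Aif1 and Wfs1 at 6 hours were -1.51, -1.32 and 0.12. With library totals alone, Ptgs2 at 12 days was 0.05 and Grik2 was 0.01, 0.21 and 0.11 at 4, 6 and 12 days; with upper-quartile factors Grik2 was 0.15 and 0.03 at 6 and 12 days. With single samples left out, Ptgs2 at 12 days ranged from -1.30 to 0.14 (without kainate sample 35), Grik4 at 4 days from -0.02 (without NaCl sample 19) to 0.53, and Grik5 at 6 hours from -0.01 (without NaCl sample 3) to 0.22.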

Other observations

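Each test here of the NaCl groups over time was fixed beforehand; the genes named were chosen after their values were seen.

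The NaCl groups themselves differed over time, for 2390 genes (9.5%) in edgeR's quasi-likelihood test. Reactive astrocyte and interferon genes had their highest mean levels in NaCl at 1 to 4 days, chemokine genes at 1 day, and dividing-cell genes at 2 and 4 days. The chemokine list was also high in NaCl at 6 hours. Its mean log2 CPM there was 1.58 to 2.18, above NaCl sample 8 at 1 day (0.48). The interferon list in NaCl at 2 days (1.60 to 3.47) overlapped that at 6 days (0.99 to 2.23). Gfap had 125 CPM at 6 hours, 816 ± 455 at 2 days (SD of 3 samples) and 211 at 12 days (adjusted p = 1.48e-04), Timp1, a protease inhibitor gene, had 0.194, 16 ± 14.5 and 0.357 (adjusted p = 6.00e-07), and Lcn2 0.289, 39.5 ± 35.9 and 0.642 (adjusted p = 1.74e-06). The mean log2 CPM of the reactive astrocyte list at 2 days was 4.43 in NaCl sample 15 against 3.34 and 2.46 in samples 13 and 14. The chemokine genes Ccl12 and Cxcl10 had 128 ± 80.9 and 114 ± 121 CPM at 1 day (SD of 3 samples) against 0.721 and 0.322 at 12 days (adjusted p = 2.43e-08 and 1.20e-05). NaCl samples 7 and 9 carried the level at 1 day, with mean log2 CPM of the interferon list at 5.10 and 5.85 against 1.65 in NaCl sample 8, while the 3 NaCl samples at 4 days lay between 2.48 and 3.62 and those at 6 hours between 0.239 and 0.508. Top2a, a gene of dividing cells, had 0.345 CPM at 6 hours, 0.255 at 1 day, 6.96 at 2 days and 0.399 at 12 days (adjusted p = 1.42e-08).

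Among the fixed lists, 22 of 22 interferon response genes differed between the NaCl groups (22 adjusted over the list alone), 18 of 23 reactive astrocyte genes (19), 19 of 24 proliferation genes (21), 17 of 28 chemokines and cytokines (19), 15 of 22 complement and antigen presentation genes (20) and 11 of 15 homeostatic microglia genes (14). Against the other NaCl groups 641 genes were higher and 1402 lower at 6 hours, 630 and 120 at 1 day, 192 and 30 at 2 days, 477 and 60 at 4 days, 29 and 4 at 6 days, and 2 and 2 at 12 days. Each kainate value is given against the NaCl group of its own time, whose level for these genes was not the same at every time.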
